A study of Homo sapiens with 4 samples.

How the data were processed

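Total RNA from 4 human samples, 2 of sorted nTreg cells and 2 of naive CD4 cells, was measured on Affymetrix arrays as biotin-labelled cRNA made from 6 micrograms of RNA, per the labels. The log2 values used here are those the authors deposited, 1 per probe set and array. That they are log2 was read from their range, and the log base, summarization, background correction and normalization are not given in the sources used here. Array medians lay within 0.1 of each other, so no normalization was added. No detection calls or background values were used here, which leaves the size of differences against dim groups uncertain.

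Probe sets were named through GEO's platform annotation, with symbols updated through Entrez IDs to the RefSeq gene table of assembly GRCh38.p14, used for names only. Of 54592 probe sets, 41074 had 1 gene, 1798 had several and 11720 had none named here. Of those with 1 gene, 41020 matched the gene table and 54 kept their older symbol. Probe sets with several genes or none were left out of the gene-level test, as were 59 for XIST, TSIX or Y-linked genes. Each gene was represented by its probe set with the highest mean over the 4 arrays, giving 19740 genes, of which 10506 had over 1 probe set.

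Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), on group alone with 2 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 19 gene lists and 10 marker lists were drawn from general knowledge of these cells and tested with camera at a preset correlation of 0.01, adjusted within each kind of list. None of the 12 gene lists that passed did so with an estimated correlation. That version of camera rests on the 2 residual degrees of freedom, so failing by it does not by itself show correlation within a list. For glycolysis and IL-2, with estimates of -0.0043 and -0.023 below the preset, camera's unadjusted p still rose from 0.012 to 0.12. The adjusted p of 0.22 shared by many lists below comes from the adjustment, over unadjusted camera p-values from 0.013 to 0.12. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named IL2RA, FOXP3 and CD4, the 10 largest changes past the threshold in each direction with no overlap between groups, and up to 4 members of each list with the smallest unadjusted p. It left out XIST, TSIX and Y-linked genes everywhere and, from the largest changes, genes whose level can follow genotype or clones. Up to 4 members were named for lists that passed or held a gene that passed, and up to 2 for the rest, a limit set after the data were seen. Other called members are given where they illustrate a list and were chosen after their values were seen. List members without a probe set of a single gene were not analysed here.

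On data simulated for this comparison with the 19740 genes, 200 of them changed, the test recovered 7.17% of genes changed by 1 log2 unit, 62% changed by 2 and 97% changed by 4, and 4.51% of its calls were unchanged genes. With no change simulated it made 0 calls. The simulated noise was normal, independent, equal in spread in both groups, and drawn from the variance model that limma fitted to these arrays. The real arrays departed from this. Their replicate differences had an SD of 0.537 in nTreg and 0.388 in naive CD4 and correlated between the groups across genes (r = 0.531). The 4.51% is therefore not an estimate of the false share of the calls below. Alternatives covered a floor on low values, quantile normalization, median centring, filters on dim genes, probe set rules, variance models, the replicate number as a block, leaving out each array, a looser threshold, an estimated correlation and fry. A second floor, leaving out genes at the floor on all 4 arrays, was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.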

Results

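Gene expression was measured on 4 Affymetrix arrays of human blood CD4 T cells that had not been stimulated. The nTreg group (naturally arising regulatory T cells, which restrain other immune cells) had 2 arrays, and the naive CD4 group (T cells that have not yet met their antigen) had 2 arrays. Per the labels, the regulatory cells were enriched on CD25 and sorted for high CD25, after which over 90% stained for FOXP3. How the naive cells were sorted is not given in the sources used here. The table held 54592 probe sets per array, with array medians of log2 values of 4.99 and 4.95 in nTreg and 4.95 and 4.92 in naive CD4. Across probe sets, Pearson's r was 0.969 between the nTreg arrays and 0.982 between the naive arrays. By a small margin, nTreg replicate 2 was closer to naive replicate 2 (r = 0.971) than to nTreg replicate 1. The median absolute differences were 0.194 and 0.250. Probe sets are not independent replicates. The number of arrays limits the precision of every value below. The labels do not say that replicates came from separate donors, so p-values measure only the spread between these 4 arrays, which could be technical.

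The comparison asked which genes differed between regulatory and naive CD4 cells. No CD4 cells that had met their antigen but were not regulatory were measured. Differences specific to regulatory cells therefore cannot be told apart from differences between naive cells and cells that have met their antigen. This holds for the gene lists below too. The largest increases in nTreg were in IL1R1, an interleukin-1 receptor, at 7.49 ± 0.52 (log2 difference ± SE, n = 2 and 2), FANK1 at 7.09 ± 0.24, the long non-coding RNA LINC01943 at 6.60 ± 0.44 and CSF2RB, a receptor chain shared by several cytokines, at 6.49 ± 0.45. The largest decreases were in NELL2, a secreted glycoprotein abundant in naive T cells, at -5.84 ± 0.48, DACT1 at -4.87 ± 0.51, the focal adhesion kinase gene PTK2 at -4.49 ± 0.37 and PCSK5 at -4.40 ± 0.28. Of 19740 genes tested with limma, 186 were higher and 175 lower in nTreg at a Benjamini-Hochberg adjusted p under 0.05, which is 1.83% of the genes. All 361 had both nTreg arrays beyond both naive arrays, as did 40.1% of all genes, where chance gives 33.3%. Among the calls, 35 were higher and 12 lower by more than 4 log2 units.

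These counts rested on the naive arrays. Without naive replicate 1, and likewise without naive replicate 2, 0 genes passed in limma, although 630 and 615 were higher and 659 and 701 lower at an unadjusted p under 0.05. All 361 genes kept their direction in both cases. With nTreg replicate 1 left out 362 genes were higher and 264 lower, and with nTreg replicate 2 left out 427 and 359. With values under the 25th percentile raised to it, 1 gene passed in each direction.

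**Figure D1:**
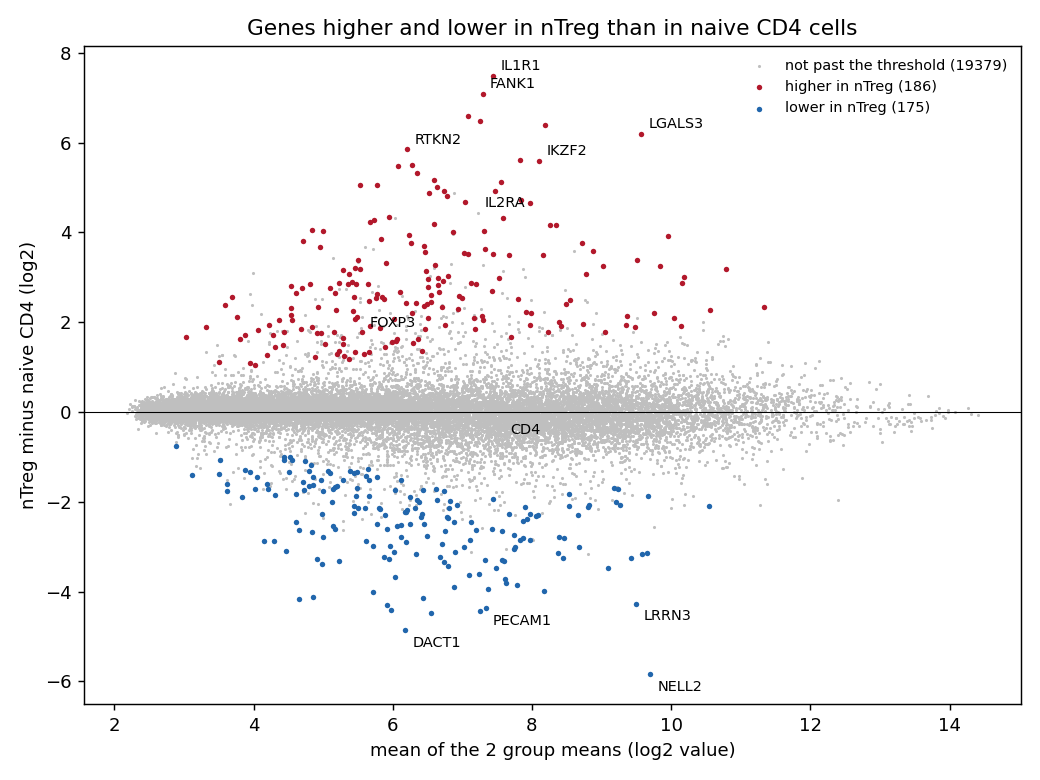
Log2 difference between nTreg and naive CD4 (vertical) against the mean of the group means (horizontal, log2 value) for the 19740 genes tested, with red for the 186 genes higher and blue for the 175 lower in nTreg at an adjusted p under 0.05. IL2RA lies at 4.44 and is grey because it did not pass.

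The sort marker and the lineage gene were read first. IL2RA, which encodes CD25, had log2 values of 11.38 and 7.50 in nTreg and 5.23 and 4.77 in naive CD4. Its difference of 4.44 ± 1.19 did not pass (adjusted p = 0.21), since the nTreg arrays differed by 3.88 log2 units. These values belong to the probe set that represented the gene. On the other IL2RA probe set, nTreg exceeded naive CD4 by 3.89. In a limma fit over probe sets its unadjusted p was 0.0030, against 0.012 for the probe set used. FOXP3, the transcription factor that defines the lineage, was higher in nTreg by 1.78 ± 0.27 (adjusted p = 0.043), with values of 6.33 and 6.57 against 4.98 and 4.37. Its other probe sets differed by 1.12 and 0.31. CD4 differed by -0.13 ± 0.71 (adjusted p = 0.97), and its sign turned to 0.79 without nTreg replicate 1 and to 0.51 without naive replicate 2.

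The next largest increases were in NIBAN1 (6.39), LGALS3 (6.20), which encodes the lectin galectin-3, RTKN2 (5.85), TRIB1 (5.61), IKZF2 (5.60), which encodes the transcription factor Helios, and the chemokine receptor gene CCR6 (5.50). Their adjusted p-values lay between 0.0043 and 0.012. The next largest decreases were in the adhesion molecule gene PECAM1 (-4.37), TGFA (-4.30), LRRN3 (-4.28), EPB41L3 (-4.17), GRB10 (-4.14) and CALD1 (-4.13), with adjusted p-values between 0.0043 and 0.032. For TGFA only 1 of 3 probe sets had this direction, for TRIB1 2 of 3 and for CALD1 9 of 11. The other probe sets of these genes, beside the one used, all lay between -0.68 and 0.14. Where signs agreed, sizes could still differ. The other probe set differed by 0.46 at IKZF2, 0.67 at RTKN2 and 1.18 at IL1R1, but by 6.17 at NIBAN1 and -4.68 at LRRN3. A background level is not given in the sources used here, so the size of a difference against a dim group is uncertain. In 188 of the 361 called genes, the lower group's mean was under 4.97, the median over probe sets.

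**Figure D2:**
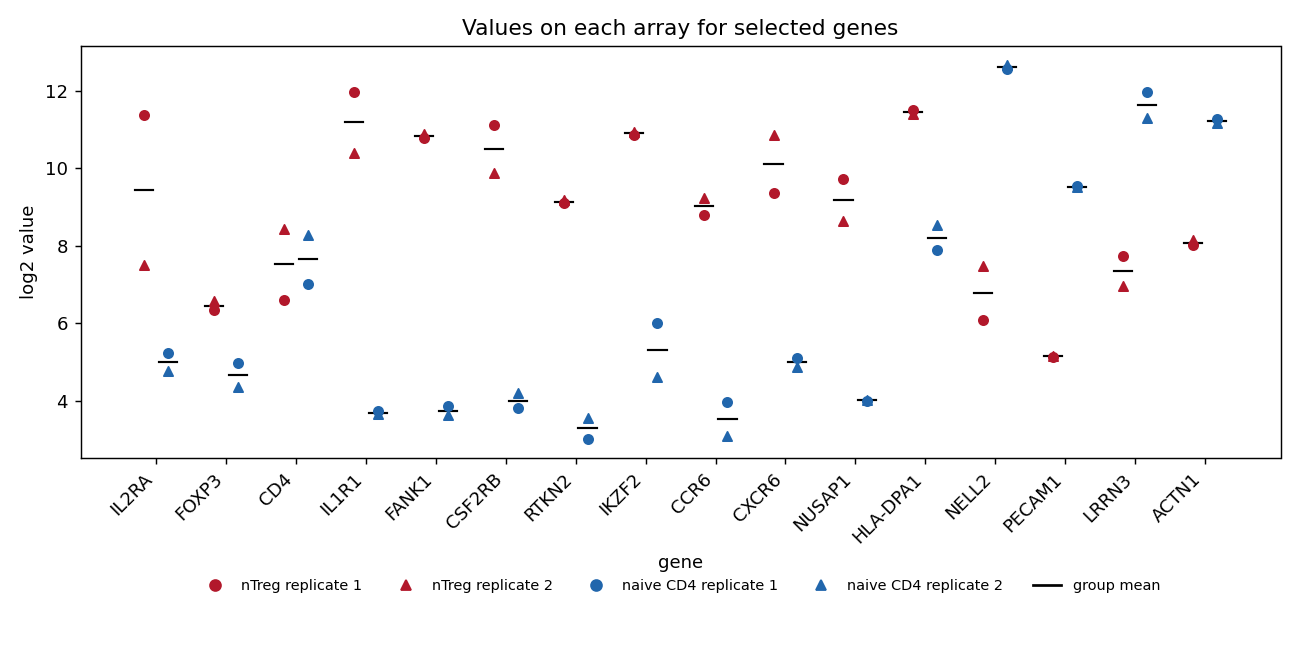
Log2 values on each array (circles replicate 1, triangles replicate 2, red nTreg, blue naive CD4, bars the group means) for 16 named genes. The nTreg arrays differed by 3.88 log2 units at IL2RA, while FANK1 read 10.79 and 10.88 in nTreg and 3.86 and 3.63 in naive CD4.

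Of 34 measured genes known as higher in human Tregs, 21 rose, 0 fell and 13 did not pass, and 31 were higher when adjusted over the list alone. The list had a median of 3.38 (camera adjusted p = 9.9e-40, and adjusted p = 0.22 with an estimated correlation). CTLA4, an inhibitory receptor, rose by 3.52 ± 0.27, TIGIT, another, by 4.65 ± 0.38, FCRL3 by 4.81 ± 0.32 and FAS, a death receptor, by 4.16 ± 0.27. Of 10 measured genes known as lower in Tregs, 4 fell and 0 rose, with 6 lower and 1 higher when adjusted over the list alone. Their median was -1.63 (camera adjusted p = 3.9e-07, and adjusted p = 0.22 with an estimated correlation). ABCB1, a drug efflux pump, differed by -3.38 ± 0.26, THEMIS, which acts in T cell receptor signalling, by -3.90 ± 0.48 and the chromatin organiser SATB1 by -2.10 ± 0.31.

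Of 16 measured naive T cell genes, 7 fell and 0 rose, and 11 were lower when adjusted over the list alone. The median was -2.08 (camera adjusted p = 8.9e-15, and adjusted p = 0.22 with an estimated correlation). ACTN1, an actin crosslinker, differed by -3.14 ± 0.24 and PECAM1 by -4.37 ± 0.23. NELL2 and SATB1 stand in this list and in the one before. Of 28 memory and effector genes, 9 rose and 0 fell, and 16 were higher when adjusted over the list alone. Their median was 1.51 (camera adjusted p = 6.9e-14, and adjusted p = 0.22 with an estimated correlation). ITGB1, the integrin beta-1 chain, rose by 2.34 ± 0.21, with 6 of 7 probe sets in this direction. Other lists share called genes too, so the list results are not independent. FAS and LGALS3 stand in the memory list and the list of genes higher in Tregs. FAS also stands in the TNF receptor and apoptosis lists below. CCR6, CXCR3 and ITGB1 stand in the memory and homing lists. CCR8 of the homing list, TNFRSF1B of the TNF receptor list and IL2RB of the IL-2 list also stand among the genes higher in Tregs.

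Of 19 measured homing receptors, 7 rose and 0 fell, and 11 were higher and 1 lower when adjusted over the list alone. The median was 1.06 (camera adjusted p = 3.5e-08, and adjusted p = 0.22 with an estimated correlation). The chemokine receptor genes CCR6, CCR2 and CXCR6 rose by 5.50 ± 0.35, 5.34 ± 0.37 and 5.13 ± 0.51. Restricted to genes above the 75th percentile of level, the list's median was 0.17 and its adjusted p 0.15.

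Of 27 measured cell cycle genes, 11 rose and 0 fell, and 17 were higher when adjusted over the list alone. The median was 1.56 (camera adjusted p = 6.3e-19, and adjusted p = 0.22 with an estimated correlation). NUSAP1, a spindle protein gene, rose by 5.17 ± 0.39, the spindle motor gene KIF11 by 4.24 ± 0.29, the checkpoint kinase gene BUB1 by 2.86 ± 0.21 and the proliferation marker gene MKI67 by 2.22 ± 0.24. None of the 7 genes MCM2 to MCM7 and PCNA, grouped after their values were seen, passed, with a median of 0.29.

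Of 9 measured HLA class II presentation genes, 1 passed and was higher, HLA-DPA1, by 3.24 ± 0.31 (adjusted p = 0.013), and 7 were higher when adjusted over the list alone. The median was 1.68 (camera adjusted p = 6.7e-07, and adjusted p = 0.22 with an estimated correlation). HLA-DOA differed by 1.24 ± 0.32, the class II chaperone gene CD74 by 1.68 ± 0.45 and HLA-DMB by 1.55 ± 0.46. B cells and monocytes carry class II too, and their markers had medians of 0.27 and -0.07, neither list passing. In naive cells these markers had median levels of 5.05 and 4.14, near or below the median over probe sets of 4.97. A small share of such cells could hardly show there.

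Of 19 TNF receptor superfamily genes, 2 rose and 1 fell, with 5 higher and 2 lower when adjusted over the list alone. TNFRSF1B, the second TNF receptor gene, rose by 3.58 ± 0.32 and the decoy receptor gene TNFRSF10D differed by -2.63 ± 0.24, while TNFRSF11A differed by 3.44 ± 0.55 (adjusted p = 0.052). The list did not pass (camera adjusted p = 0.051), but passed with quantile normalization (adjusted p = 0.031), median centring (adjusted p = 0.029), genes above the median level (adjusted p = 0.037), the mean of all probe sets (adjusted p = 0.035), without nTreg replicate 1 (adjusted p = 0.0093) and by fry (adjusted p = 0.040). Its adjusted p ran from 0.0093 to 0.79 over 17 alternatives. Of 17 apoptosis genes, 1 rose, FAS, and 3 were higher and 2 lower when adjusted over the list alone. CASP8, an initiator caspase gene, differed by 1.35 ± 0.26, CASP10 by -1.25 ± 0.23 and TNFRSF10B by -1.16 ± 0.26. CASP10 and TNFRSF10B were each lower on 2 of 4 probe sets. The list's median was 0.41 (camera adjusted p = 0.0074, and adjusted p = 0.31 with an estimated correlation). It did not pass without nTreg replicate 1 (adjusted p = 0.061) or without naive replicate 2 (adjusted p = 0.088).

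Of 16 IL-2 and STAT5 signalling genes, 1 rose, also when adjusted over the list alone. It was IL2RB, the receptor's beta chain, at 3.26 ± 0.42. PIM3 differed by 0.61 ± 0.26 and OSM by 0.40 ± 0.19. The list's median was 0.41 (camera adjusted p = 0.020, and adjusted p = 0.22 with an estimated correlation). It did not pass without nTreg replicate 1 (adjusted p = 0.10) or without naive replicate 2 (adjusted p = 0.088). In the immediate early and NF-kB list, FOSL2 rose by 2.99 ± 0.24 and was 1 of 23 genes to pass, also when adjusted over the list alone, while NFKBIA, KLF6 and MYC differed by -0.91 ± 0.32, 0.77 ± 0.35 and -1.13 ± 0.53. That list did not pass (camera adjusted p = 0.96).

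Among the metabolic and housekeeping lists, no single gene passed. The 15 glycolysis genes had a median of 0.46 (camera adjusted p = 0.020, and adjusted p = 0.22 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. SLC2A3, a glucose transporter gene, differed by 1.17 ± 0.31, PGAM1 by 0.64 ± 0.22, GAPDH by 1.04 ± 0.39 and SLC2A1 by 0.90 ± 0.35. The list did not pass without nTreg replicate 2 (adjusted p = 0.17), without naive replicate 1 (adjusted p = 0.075), with the mean of all probe sets (adjusted p = 0.062) or without probe sets that can match several transcripts (adjusted p = 0.26). The 19 ribosomal protein genes had a median of -0.27, with 18 below 0 (camera adjusted p = 8.6e-06, and adjusted p = 0.22 with an estimated correlation) and 0 past the threshold when adjusted over the list alone. RPL3 differed by -0.68 ± 0.18, RPL19 by -0.65 ± 0.19, RPL11 by -0.66 ± 0.22 and RPS14 by -0.51 ± 0.20. The 9 heat shock genes had a median of -0.39 (camera adjusted p = 0.019, and adjusted p = 0.36 with an estimated correlation), with 1 lower when adjusted over the list alone. BAG3 differed by -1.87 ± 0.35, HSPB1 by -0.73 ± 0.27, DNAJA1 by -0.66 ± 0.28 and HSPD1 by -0.39 ± 0.21. The heat shock list did not pass without nTreg replicate 2 (adjusted p = 0.079), without naive replicate 1 (adjusted p = 0.060) or above the 75th percentile of level (adjusted p = 0.098), and its median turned to 0.03 without probe sets that can match several transcripts. The 20 oxidative phosphorylation genes had a median of -0.04 (camera adjusted p = 0.83), with COX5A at 1.12 ± 0.29 and COX4I1 at -0.44 ± 0.19 and 0 past the threshold when adjusted over the list alone.

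Genes of T cell signalling and cytokines gave no single gene past the threshold over all genes. The 24 T cell receptor signalling genes had a median of -0.12 (camera adjusted p = 0.36), with PTPN22, a phosphatase gene, at 2.14 ± 0.74 and LAT at -0.59 ± 0.21 and 0 past the threshold when adjusted over the list alone. The 14 TGF-beta signalling genes had a median of -0.28 (camera adjusted p = 0.17, and 0.032 without nTreg replicate 2). Adjusted over the list alone, 2 were higher and 3 lower, among them LRRC32 at 1.87 ± 0.40 and SMURF2 at -1.85 ± 0.37. The 22 interferon-stimulated genes had a median of 0.13 (camera adjusted p = 0.79), with 1 higher and 1 lower when adjusted over the list alone. OAS1 differed by 2.00 ± 0.36 and IFIT2 by -1.98 ± 0.34. The 16 cytokine genes had a median of -0.01 (camera adjusted p = 0.79) and 0 past the threshold when adjusted over the list alone, with IL12A at 0.29 ± 0.16 and IL10 at 0.34 ± 0.23.

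**Figure D3:**
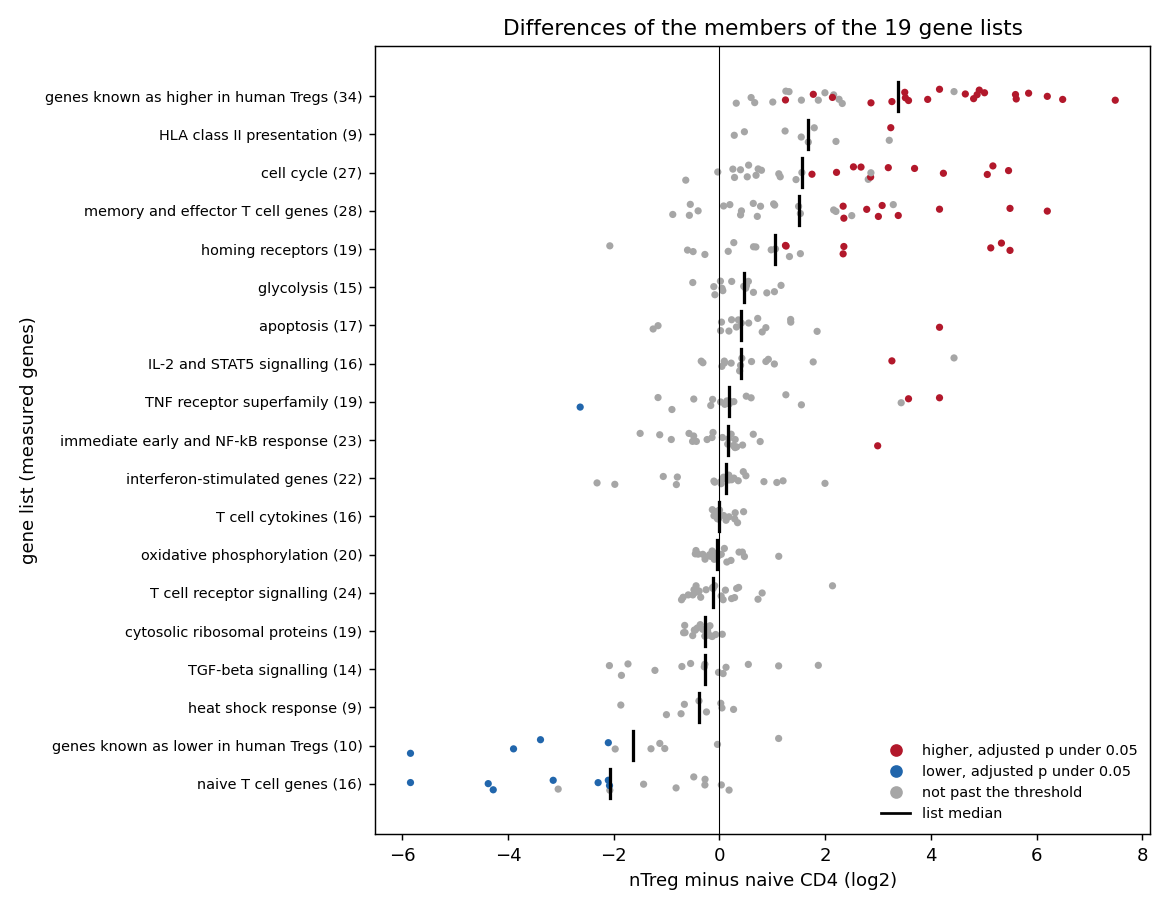
Log2 difference between nTreg and naive CD4 for each measured member of the 19 gene lists (points, coloured where the adjusted p over all genes was under 0.05), with the list median as a bar and the number of measured genes in parentheses. Medians ran from -2.08 for naive T cell genes to 3.38 for genes known as higher in human Tregs.

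Marker lists of CD4 T cells and of other blood cells had medians from -0.39 to 0.32, with larger differences at single genes. None of the 10 marker lists passed, with camera adjusted p-values from 0.099 to 0.99. The medians were -0.39 for CD4 T cells, 0.32 for CD8 T cells, 0.27 for B cells, -0.07 for monocytes, 0.07 for natural killer cells, 0.16 for plasmacytoid dendritic cells, 0.10 for platelets, 0.31 for erythroid cells, 0.19 for basophils and mast cells and 0.18 for neutrophils. Of their genes, 1 passed over all genes, PRF1, which encodes the cytotoxic protein perforin, at 2.23 ± 0.26 (adjusted p = 0.022). Its other probe set differed by 0.39. Of the other marker genes, CD79B differed by 0.93 ± 0.22, IRF8 by -1.05 ± 0.24 and TRAT1 by -1.65 ± 0.31.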

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

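The 2 results here were picked out because they are signals in probe sets that the gene-level comparison did not use. In a limma fit over all probe sets, 21 of the 11720 probe sets with no gene named here were higher in nTreg at an adjusted p under 0.05, and 30 were lower, with differences up to 4.74 and down to -4.06 log2 units. Of the 1798 probe sets with several genes, 6 were higher and 5 lower, with differences up to 5.67 and down to -3.95. No explanation was tested for either.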

How the results depend on the processing

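All 361 genes kept their direction under every refit that tested all of them. Without probe sets named _x_at or _s_at, 306 of 311 tested genes did. Against 186 higher and 175 lower genes, limma gave 1 and 1 with values floored at the 25th percentile, where 2631 genes have no spread, and 121 and 100 with those genes left out, an alternative added after seeing the data. It gave 61 and 55 above the 75th percentile of level, where fewer genes were tested, 116 higher without _x_at and _s_at probe sets, 104 lower without a trend, and 281 and 282 at an adjusted p under 0.10. With 1 array left out, the counts ran from 0 to 427 higher and 0 to 359 lower. Without a naive array the spread comes from the nTreg pair alone, whose replicates differed more (SD 0.537 against 0.388 between the naive arrays). A lone array is assumed to vary like the other group. All 48 genes named in the text that passed the threshold lost the call without 1 of the naive arrays, and 0 reversed. Of 63 named genes that did not pass, 25 passed under some alternative: 22 with the replicate block, 11 without nTreg replicate 1 and 9 without nTreg replicate 2, IL2RA and TNFRSF11A each time, and TNFRSF11A also with quantile normalization and with median centring.

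With the replicate number as a block, 592 genes were higher and 624 lower. The replicate differences of the groups correlated across genes (r = 0.531), but 2 pairs with no stated shared donor do not establish pairing.

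Of 12 gene lists past the threshold, 0 passed with an estimated correlation, a test with only 2 degrees of freedom here. By contrast 6 lists passed by fry, 5 of them among the 12. By fry the lists of genes lower in Tregs, class II, apoptosis, IL-2, glycolysis, ribosomal proteins and heat shock did not pass (adjusted p from 0.052 to 0.20). With 1 array left out, 10 to 11 lists passed. The homing and heat shock lists did not pass above the 75th percentile of level. The TNF receptor list, which had not passed, passed under 6 of 17 alternatives (fry among them), and the TGF-beta list without nTreg replicate 2.

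Among the genes and lists named in the text, reversed values belonged to the heat shock list, which had passed, and to others that had not. Without _x_at and _s_at probe sets HSPD1 was 0.032, CD8B -0.017, TUBB1 0.098, the heat shock list 0.032 and the cytokine list 0.080. With the mean of probe sets TUBB1 was 0.00063 and the cytokine list 0.079. The cytokine list was 0.12 above the median level and 0.033 with floored values and genes at the floor left out, and the TNF receptor list was -0.071 above the 75th percentile. With 1 array left out, CD4 ran from -1.05 to 0.79, CD8B from -0.35 to 0.86, FGFBP2 from -0.48 to 0.033, SOCS2 from -1.25 to 3.10, SOCS3 from -0.98 to 3.05, CISH from -0.93 to 1.70, the cytokine list from -0.052 to 0.094, the immediate early list from -0.045 to 0.14 and the oxidative phosphorylation list from -0.090 to 0.19. The cause was not tested.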

Other observations

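The family test and the tests of explanations in this part were chosen after the results they bear on had been seen, while the calls over all genes and the list tests with an estimated correlation and by fry were planned.

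Among gene families defined by symbol, the kinesin genes had 5 of 42 measured higher in nTreg (KIF11, KIF15, KIF20A, KIF23 and KIF4A), a share above that of other genes by Fisher's exact test (adjusted p = 0.012 over 129 families in both directions). KIF15 differed by 3.15, KIF23 by 1.88, KIF20A by 1.78 and KIF4A by 1.22 log2 units. KIF11 also stands in the cell cycle list, and the test treats genes as independent, so this result is not separate support for that list. The annexin family had 3 of 17 genes higher, ANXA2, ANXA2P2 and ANXA4, and did not pass by Fisher's exact test (adjusted p = 0.066).

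The 9 HLA class II genes lay above the naive mean by a median of 0.91 in nTreg replicate 1 and 2.19 in nTreg replicate 2, but 1 of them passed over all genes and the list did not pass with an estimated correlation (adjusted p = 0.22) or by fry (adjusted p = 0.096). B cells, monocytes or dendritic cells in the sort would bring their own transcripts. The 26 markers had a median excess of 0.00134 in nTreg replicate 2, and this check used that array only. B cell, monocyte and plasmacytoid dendritic cell medians were 0.18, -0.23 and -0.03, with a highest value of 0.74. LYZ and CST3 of conventional dendritic cells stand in the monocyte list. Over both nTreg arrays, 9 of 10 B cell markers and 2 of 11 monocyte markers lay above the naive mean. In naive cells the B cell and monocyte lists had median levels of 5.05 and 4.14, near or below the median over probe sets of 4.97. A small share of such cells could therefore hardly show, so this explanation stays open. Donor sequence variants under the probes would spare the little-variable genes, but HLA-DRA, HLA-DMA, HLA-DMB, HLA-DOA and CD74 had a median difference of 1.68 and were higher in both nTreg arrays than in both naive arrays. None of these 5 passed over all genes (limma adjusted p from 0.19 to 0.34), and 40.1% of all genes had such non-overlapping groups. The 2 HLA genes that passed as higher, HLA-DPA1 and HLA-DQA1, lie outside these 5. Variants under the probes of those 2 stay open. No biological explanation was tested.

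In the cell cycle list, the 20 genes other than the MCM genes and PCNA had a median difference of 2.61, with 11 past the threshold. The 7 MCM genes and PCNA had 0.29 and 0. This split was made after the values were seen, as was the choice to name RRM2 and TYMS, DNA synthesis genes among the 20. It sets genes with a median naive level of 4.435 against genes at 8.607. The 3 of the 20 at or above the lowest level of the 7 had a median difference of 0.73. For RNA from other dividing blood cells, 38 markers of B cells, monocytes, natural killer cells, plasmacytoid dendritic cells and basophils were read. Their median difference was 0.054, with PRF1 highest at 2.23, and B cell and monocyte medians of 0.27 and -0.07. None of these markers stands in a gene list. Only 13 had a naive mean above the median of all probe sets, so a small share of such cells could hardly show and cannot be excluded. CD8 T cell and erythroid markers, with medians of 0.32 and 0.31, were not among the 38. A high starting level of the MCM genes and PCNA on the log scale stays open, since their median added linear signal was 0.292 times that of the other genes, with single genes from -393.4 to 401. Other dividing CD4 T cells in the sort were not tested.

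On the probe set that represented the gene, IL2RA was 3.88 log2 units lower in nTreg replicate 2 than in nTreg replicate 1. The gap was not examined on its other probe set. A lower share of Treg cells in replicate 2 would lower the other Treg genes too, yet all 33 others measured had a median gap of 0.163 (interquartile range 1.28, from -1.99 to 2.31; medians of 0.203, 0.651 and 0.442 over the 28, 23 and 18 genes more than 1, 2 and 3 above the naive mean in replicate 1), and 15 of them, FOXP3 included, were higher in replicate 2. A difference shared by arrays of the same replicate number stays open: the naive arrays differed by 0.456 at IL2RA, but its naive mean of 5.001 was near the median over probe sets of 4.972, where a gap could hardly show. The other 15 IL-2 and STAT5 genes had a median gap of 0.233 in nTreg and 0.1045 between the naive arrays, at percentiles 94.67 and 71.31 of 10000 random lists of similar level, with 7 of them higher in nTreg replicate 2 (gaps down to -1.838) and 4 above 2, SOCS1, SOCS2, SOCS3 and CISH at 3.25, 4.34, 4.03 and 2.63, which between the naive arrays were 0.96, 2.86, 0.78 and 1.90, these 4 picked after their values were seen. A biological difference between the nTreg samples was not tested.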
